A study of Mus musculus with 19 samples.

How the data were processed

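The series holds 19 arrays of an Affymetrix mouse genome type, 18 from cells of postnatal day 3 limbs and 1 from adult cells. According to the labels, limb tissue of a pooled litter was dissociated mechanically and with collagenase, and cells were sorted by antibodies. RNA was amplified in a pair of rounds, and biotin-labelled product was hybridized and scanned with GCOS software. The deposited table gives log2 expression levels for 45101 probe sets and the values were read as log2, ranging from 2.55 to 14.6, because another log base would exceed the range of a scanner. How the authors got from scans to these deposited log2 values is not given in the sources used here. The distributions of the arrays differed, with medians from 5.60 to 6.02. By a rule fixed before the data were examined, arrays whose medians differ by more than 0.1 were quantile normalized over the 19 arrays with normalizeBetweenArrays. No filter on low values was used.

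Of the probe sets, 64 were controls and left out of the tests, 34945 had 1 gene symbol in the table used, 932 had several and 9160 had none. For each of 18193 genes the probe set with the highest mean over the 18 neonatal arrays stood for the gene, among those with 1 symbol. Gene names came from the probe set table given with the series. Arrays carry no counts, so no depth is given, and 3 arrays per population limit the precision.

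Arrays were grouped by the population field of the labels. Replicates 2 and 3 of Thy-6C3+CD105- have titles that name Thy+ instead, and a fit grouped by title was among the alternatives. That fit leaves a single array in Thy-6C3+CD105-. The array labelled adult, whose source field names sternum and ear and whose tissue field names limbs, entered no test. Expression was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per population over the 18 arrays (12 residual degrees of freedom, prior degrees of freedom 5.38), contrasts for 7 single-antigen steps and 2 interactions, and eBayes with a trend. Tests were two-sided. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 within its contrast, and a moderated F-test compared all 6 populations.

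Gene lists were fixed before the data were examined. Of their 578 members 537 were named by the table, and 31 lists were tested with limma camera at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. No list was chosen on these arrays.

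Named genes followed a rule fixed beforehand. It took the 6 largest rises and 6 largest falls among genes past the test whose groups did not overlap and whose higher mean lay above the median gene mean of 6.76. It added up to 4 called members of each list that passed camera or had at least 3 called members, the sorted antigens, and for the interactions 4 genes per direction. For space, not all of them are named. Genes of the keratinocyte and pericyte lists in the closing section were chosen after their values were seen. So were Col10a1 and Ihh in the CD105 step of Thy-6C3- cells, Col10a1 in the interactions and Cspg4 in the Thy step.

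The poly-A control probe sets, which enter RNA before amplification, split the neonatal arrays at 6.14 log2 into a set of 11 high and a set of 7 low arrays, with arrays of every population in both. This split was found in the data, and each comparison was repeated within each set, with 5 residual degrees of freedom in the high and 1 in the low set. Most populations had a single array in the low set, as had Thy-6C3-CD105- in the high set. Where a group was left with a single array, no count of genes is given.

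The fits were tested on simulated arrays of the same layout, with normal noise drawn independently for each gene and array. The simulated arrays lack deviations shared between arrays or genes, so the shares below may not hold for the real arrays. For the Thy steps 50% and 53% of genes changed by 1 and 94% and 92% of genes changed by 2 on the log2 scale were recovered, and 12 and 8 of 17968 unchanged genes were called. For the 6C3 steps 49% in both and 94% and 90% were recovered, with 5 and 8 false calls. For the CD105 steps in Thy-6C3-, Thy+6C3- and Thy-6C3+ cells 54%, 44% and 49%, and 86%, 94% and 92%, were recovered, with 5, 4 and 8 false calls.

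Alternatives fixed beforehand or added after seeing the data changed the scaling, the set of genes, the choice of probe sets, the variance model, array weights, a replicate block, a spike-in block, the grouping by title and the arrays used. Each array was also left out in turn, and the closing section gives the effects. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.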

Results

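The series measured gene expression in skeletal progenitor populations sorted by flow cytometry from the fore and hind limbs of wild-type mice at postnatal day 3. All cells had passed a gate that excluded CD45, Ter119 and Tie2 and required integrin alpha V. Combinations of 3 further antigens, Thy, 6C3 and CD105, then defined 6 populations with 3 arrays each: Thy-6C3-CD105-, Thy-6C3-CD105+, Thy+6C3-CD105+, Thy+6C3-CD105-, Thy-6C3+CD105+ and Thy-6C3+CD105-. Another array, labelled as adult Thy+6C3+CD105+ cells, enters no test. The deposited medians of the 19 arrays lay between 5.60 and 6.02 on the log2 scale. The number of arrays limits the precision. The question addressed is how the populations differ in expression when 1 surface antigen changes, so each comparison is a step, the antigen-positive minus the antigen-negative population. Log2 changes are given with the SE of the fit and levels with the SD of the 3 arrays. Adjusted p values are from limma, over 18193 genes unless another set is named.

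The genes of the sorted antigens followed the population names for Thy and 6C3, and for CD105 in Thy- cells. Thy1, which encodes Thy, stood at 10.34 ± 0.14 (SD, n = 3) in Thy+6C3-CD105+ cells and at 5.46 ± 0.48 in Thy-6C3-CD105+ cells. Enpep, the aminopeptidase recognized by the 6C3 antibody, stood at 10.84 ± 0.13 in Thy-6C3+CD105+ and 7.28 ± 0.37 in Thy-6C3-CD105+ cells. Eng, which encodes CD105, differed by 1.45 ± 0.30 in Thy-6C3- cells, 0.59 ± 0.30 in Thy+6C3- cells and 1.26 ± 0.30 in Thy-6C3+ cells. None of these Eng differences passed the test (adjusted p = 1, 0.254 and 1). Eng still did not overlap between CD105- and CD105+ arrays in Thy-6C3- cells, at 6.95 to 7.35 against 8.39 to 8.83. The same held in Thy-6C3+ cells, at 6.65 to 7.82 against 8.17 to 8.76. With the mean of its probe sets Eng passed in all 3 CD105 steps. In Eng the array labelled Thy+6C3-CD105- replicate 3 goes against its label, at 8.58, where its replicates have 7.51 and 7.61. The Thy+6C3-CD105+ arrays have 8.75, 8.38 and 8.34, and without the array in doubt the Eng difference in Thy+6C3- cells was 0.926. Rgs5 and Epas1 go with its label, at 8.63 and 5.43, where its replicates have 8.26 and 8.89, and 6.38 and 6.21. The Thy+6C3-CD105+ arrays had at least 12.06 and 9.66. Both genes were called in the CD105 step by a fit that includes this array. Enpep on the adult array, labelled 6C3+, was 8.43, within the range of the neonatal 6C3- arrays (6.20 to 8.83) and below the 6C3+ arrays (10.69 to 11.24). Replicates 2 and 3 of Thy-6C3+CD105- are called Thy+ in their titles and Thy- in their population field. Their Thy1 levels were 5.78 and 5.95, within 0.6 of the Thy- population means and more than 4 below the Thy+ means, and they are grouped as Thy- here. Cd200, also among the stained antigens, fell in both Thy steps, by 1.77 on the log2 scale among CD105+ and by 1.97 among CD105- cells (adjusted p = 0.00927 and 0.00323). Tek, which encodes the excluded antigen Tie2, rose in both Thy steps, by 1.11 ± 0.17 and 1.51 ± 0.17 (adjusted p = 0.000349 and 1.45e-05), from 4.84 and 4.88 to 5.96 and 6.39, levels below the median gene. Among all 6 populations, 1845 genes differed by the moderated F-test. The 11 arrays with high and the 7 arrays with low poly-A control signal form 2 sets that cross every population. Each set left some population with a single array, so no count is given within them. With array weights 3898 genes differed.

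**Figure D1:**
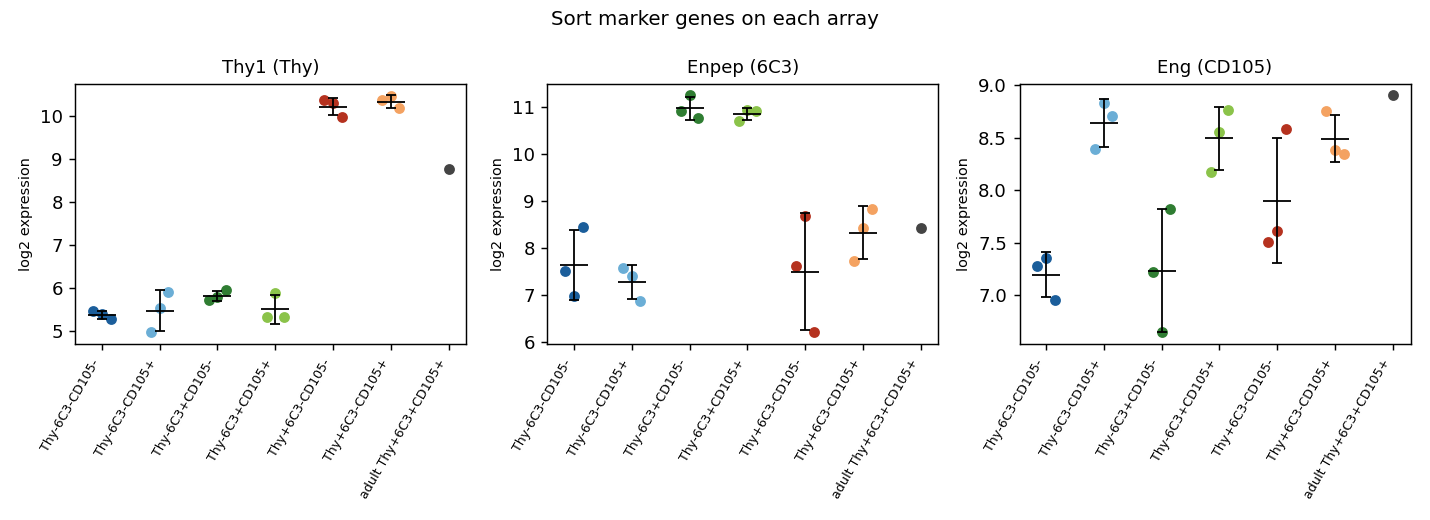
Log2 expression of Thy1, Enpep and Eng on each array, by population, with the mean and SD of the 3 neonatal arrays in black and the adult array in grey. Among the neonatal arrays Thy1 separates Thy+ from Thy- and Enpep separates 6C3+ from 6C3-, while Eng overlaps between the Thy+6C3- populations and Enpep of the adult array lies among the 6C3- arrays.

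In the Thy step in 6C3-CD105+ cells, cartilage genes were lower in the Thy+ population. All 23 members of the chondrocyte list fell over all genes, and all 23 adjusted over the list alone, with a median log2 change of -2.78. Among them were Snorc, a cartilage proteoglycan (-4.28 ± 0.43, adjusted p = 4.35e-06), Matn3, a matrilin of cartilage matrix (-3.93 ± 0.23, adjusted p = 1.14e-08), Col9a2, a chain of collagen IX (-3.88 ± 0.21, adjusted p = 7.40e-09), and Epyc, a small proteoglycan of cartilage (-3.81 ± 0.26, adjusted p = 1.03e-07). Matn3 stood at 8.41 ± 0.36 in Thy+6C3-CD105+ and at 12.35 ± 0.06 in Thy-6C3-CD105+ cells. Of the 8 members of the hypertrophic chondrocyte list, 3 fell over all genes and 6 adjusted over the list alone. These included Col10a1, the collagen of hypertrophic cartilage, by 2.63, Ihh, a hedgehog ligand of the growth plate, by 2.13, and Panx3, a channel protein of cartilage and bone, by 5.05. Panx3 was lower in both Thy steps and both 6C3 steps on the probe set used, and its remaining probe set, below the median level, changed by 0.06 to 0.28 when shared probe sets were left out. In the osteoblast list of 18, Smpd3, an enzyme needed for mineralization (-3.28 ± 0.26, adjusted p = 3.49e-07), and Ibsp, a sialoprotein of bone matrix (-4.37 ± 0.82, adjusted p = 0.00207), fell. Over the whole list 5 members fell and 2 rose, including the cadherin gene Cdh11 (1.56 ± 0.28), and adjusted over the list alone 8 fell and 2 rose.

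Mural and fibrous genes rose in the same step. Of 12 pericyte and smooth muscle genes 9 rose and 1 fell, over all genes and adjusted over the list alone. The member that fell was Cspg4, from 12.22 to 10.68. The rises included Rgs5, a regulator of G protein signalling in pericytes, from 8.86 ± 0.28 to 12.22 ± 0.17, Notch3, a receptor of mural cells (3.60 ± 0.42), the potassium channel gene Kcnj8 (3.06 ± 0.22) and Mylk, which encodes myosin light chain kinase (2.57 ± 0.25). Of 20 tendon and fibrous genes 8 rose and 1 fell (12 and 1 adjusted over the list alone), with Kera, keratocan, at 12.46 ± 0.30 against 9.45 ± 0.16, Dpt, dermatopontin, at 12.44 ± 0.09 against 10.03 ± 0.30, and Mfap5, a microfibril gene, 2.32 ± 0.29 higher. Among 19 haematopoietic support genes 7 rose and 1 fell (8 and 1 adjusted over the list alone), including the chemokine gene Cxcl12 (2.39 ± 0.27, adjusted p = 1.43e-05), the adhesion gene Vcam1 (1.93 ± 0.20, adjusted p = 4.35e-06) and Lepr, the leptin receptor (3.21 ± 0.78). The Lepr call was lost without replicate 3 of either population. The peptidase gene Dpep1 (4.44 ± 0.34), the TEAD cofactor gene Vgll3 (4.36 ± 0.36), Ifitm1 (4.02 ± 0.38), the mesenchymal transcription factor gene Twist2 (3.69 ± 0.30) and the cytokine gene Il33 (3.56 ± 0.44) were the other largest rises by the rule for named genes. Calml3, related to calmodulin, fell by 4.16, Scin, an actin-severing protein gene, by 4.00, and the forkhead gene Foxa3 by 4.23.

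Smaller groups also moved in this step. Of 15 endothelial genes 3 rose and 1 fell (4 and 1 adjusted over the list alone), with Esam at 2.32 ± 0.18, Sox18 at 1.43 ± 0.32 and Flt1 at 1.05 ± 0.24, and the list did not pass camera (adjusted p = 0.461). The Sox18 call was lost without replicate 1 of either population and the Flt1 call without Thy+6C3-CD105+ replicate 1. Of 13 interferon response genes 4 rose (6 adjusted over the list alone), among them Ifit2 (1.80 ± 0.33), and of 18 metalloprotease and inhibitor genes 5 rose (10 rose and 2 fell adjusted over the list alone), among them Mmp23 (1.87 ± 0.18). Of 16 angiogenic factors 4 rose (6 adjusted over the list alone), including Angpt2 (1.47 ± 0.23). Of 14 Hedgehog pathway genes 3 fell, over all genes and adjusted over the list alone, including Hhip (-1.41 ± 0.27). Hypoxia and glycolysis genes went lower, 4 of 18 falling and 1, Car9, rising by 1.31 (7 and 1 adjusted over the list alone). Among immediate early genes, which respond to tissue dissociation as well as to growth signals, 10 of 18 fell (12 adjusted over the list alone), with Fosb at -2.91 ± 0.48 and Junb at -2.17 ± 0.33. These genes were highest in the same Thy-6C3- populations in which the cartilage genes were highest.

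In this step 1211 genes passed the test, 733 higher and 478 lower in Thy+ cells, and 834 of them changed by at least 2-fold. The groups did not overlap for 26.2% of all genes, where chance gives 10%. By camera the calls held with the preset and with an estimated correlation for the chondrocyte (adjusted p = 5.78e-53 and 5.28e-05), hypertrophic chondrocyte (2.27e-09 and 0.000449), pericyte and smooth muscle (2.47e-15 and 0.00134), tendon and fibrous (2.90e-09 and 0.0129), haematopoietic support (0.00176 and 0.0131), interferon (2.67e-06 and 0.00150), metalloprotease (1.76e-05 and 0.0193), angiogenic (0.000573 and 0.0120), Hedgehog (0.00286 and 0.0168), hypoxia (0.000638 and 0.0422), immediate early (3.52e-12 and 0.0120) and osteoblast lists (0.000573 and 0.0368). The proliferation list, with 3 of 25 members higher (5 adjusted over the list alone), lost its call (adjusted p = 9.73e-07, and adjusted p = 0.0741 with an estimated correlation). So did the limb and Hox (0.0391), adipocyte (0.0440) and TGF beta lists (0.0440), with adjusted p = 0.211, 0.108 and 0.205 with an estimated correlation. The hypertrophic chondrocyte and interferon calls were lost over the upper part of genes by mean level. Within the high poly-A set 761 genes passed. The low set left a single array in each group, and its log2 changes correlated with those of the high set at r = 0.731 across genes. Without Thy-6C3-CD105+ replicate 3 the count was 781, and with array weights it was 2889. With the compared populations alone it was 1813.

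In the Thy step in 6C3-CD105- cells, both cartilage lists were lower in the Thy+ population as well. All 23 chondrocyte genes fell (median -2.89) and all 8 hypertrophic chondrocyte genes fell (median -2.57), over all genes and adjusted over the list alone. Matn1, another matrilin, stood at 6.13 ± 0.46 in Thy+6C3-CD105- and 11.62 ± 0.11 in Thy-6C3-CD105- cells, a change of -5.50 ± 0.34 (adjusted p = 1.16e-08). Col9a2 (-4.57 ± 0.21), Fgfr3, an FGF receptor of growth plate cartilage (-4.54 ± 0.38), Matn3 (-4.20 ± 0.23), the collagenase gene Mmp13 (-3.43 ± 0.41), Col10a1 (-2.93 ± 0.27) and Ihh (-2.58 ± 0.23) fell as well. Of 18 osteoblast genes 6 fell (8 fell and 1 rose adjusted over the list alone), including Ibsp (-5.11 ± 0.82), Smpd3 (-3.65 ± 0.26) and Phex, a regulator of phosphate handling in bone (-2.80 ± 0.46). In the BMP pathway list of 28, 9 fell and 1 rose (9 and 2 adjusted over the list alone), led by the ligand genes Bmp2 (-4.18 ± 0.51) and Gdf10 (-2.71 ± 0.15). Frzb, a secreted Wnt antagonist, fell by 5.27 and S100b, a calcium-binding protein gene of glia and cartilage, by 4.90. Prg4, which encodes lubricin of joint surfaces, fell by 2.72 here and by 2.47 in the Thy step among CD105+ cells.

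Some fibrous and epithelial genes were higher in Thy+6C3-CD105- cells, though neither list kept its camera call with an estimated correlation. Of 20 tendon and fibrous genes 9 rose and 1 fell (13 and 1 adjusted over the list alone), including Kera (2.75 ± 0.26), Mfap5 (2.49 ± 0.29), Dpt (2.31 ± 0.32) and Thbs4, a thrombospondin of tendon (1.96 ± 0.26). Of 12 keratinocyte genes 4 rose, over all genes and adjusted over the list alone, with Krt5 at 8.84 ± 0.48 against 6.53 ± 0.23, Krt15 at 7.59 ± 0.95 against 4.84 ± 0.13 and Krt14 at 6.86 ± 0.74 against 4.77 ± 0.12. Of 25 proliferation genes 13 rose (16 adjusted over the list alone), among them Mki67, a marker of cycling cells (1.21 ± 0.24), and Kif23, a kinesin of cell division (1.29 ± 0.28), and both calls were lost when the fit used the arrays of the compared populations only. Of 13 interferon genes 6 rose (9 rose and 1 fell adjusted over the list alone), including Ifi27l2a, at 7.29 ± 0.36 against 5.79 ± 0.21. Of 16 myeloid genes 4 rose (5 adjusted over the list alone), with Laptm5, a lysosomal protein gene of blood cells, at 8.73 ± 0.90 against 6.44 ± 0.18. The receptor gene Uts2r (3.43 ± 0.40), the pentraxin gene Ptx4 (3.41 ± 0.26), Il33 (3.02 ± 0.44), the sulfotransferase gene Chst5 (2.85 ± 0.23) and Fgf9, a growth factor gene (2.71 ± 0.38), rose too. Among immediate early genes 13 of 18 fell (15 adjusted over the list alone), with Atf3 at -3.11 ± 0.61 and Fosb at -2.88 ± 0.48.

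In this step 3271 genes passed the test, 1915 higher and 1356 lower, and 1702 changed by at least 2-fold, while 34.7% of genes did not overlap between the groups. Camera called the chondrocyte (adjusted p = 1.72e-39 and 0.000121 with an estimated correlation), hypertrophic chondrocyte (1.60e-13 and 0.000118), immediate early (3.45e-12 and 0.0180) and BMP lists (3.86e-06 and 0.00763) with both settings. The calls of the proliferation, tendon, osteoblast, hypoxia, interferon, keratinocyte and Hedgehog lists (adjusted p = 0.000119, 0.000162, 0.000264, 0.000437, 0.0194, 0.0230 and 0.0261) were lost, with adjusted p = 0.193, 0.0885, 0.0544, 0.0567, 0.0567, 0.0757 and 0.0663 with an estimated correlation. The Hedgehog call was lost without Thy-6C3-CD105- replicate 2, and the myeloid list did not pass (adjusted p = 0.113). The split by direction depended on the scaling. The median of all genes moved from 0.13 to 0.09 with the values as deposited and to -0.05 with a common median only. The split then became 1648 higher and 2028 lower, and 928 higher and 2640 lower. It was 584 and 598 with the compared populations alone and 762 and 787 without Thy-6C3-CD105- replicate 3. Each poly-A set left a single array in a group of this step, and the log2 changes of the 2 sets correlated at r = 0.655 across genes. The count was 2022 without Thy-6C3-CD105- replicate 1, 1549 without its replicate 3, 1767 without Thy+6C3-CD105- replicate 3, 2118 without the 2 arrays with extreme hybridization controls and 1182 with the compared populations alone. With its compared populations alone the Thy step in CD105+ cells gave 1813. The order of the 2 Thy steps by count thus depended on the arrays used for the fit.

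The 2 Thy steps share no arrays. Of their called genes 413 were higher in both, where independent calls give 77.2, 390 were lower in both, where they give 35.6, and 3 went opposite ways. Across genes the log2 changes correlated with r = 0.489, genes not being independent replicates.

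**Figure D2:**
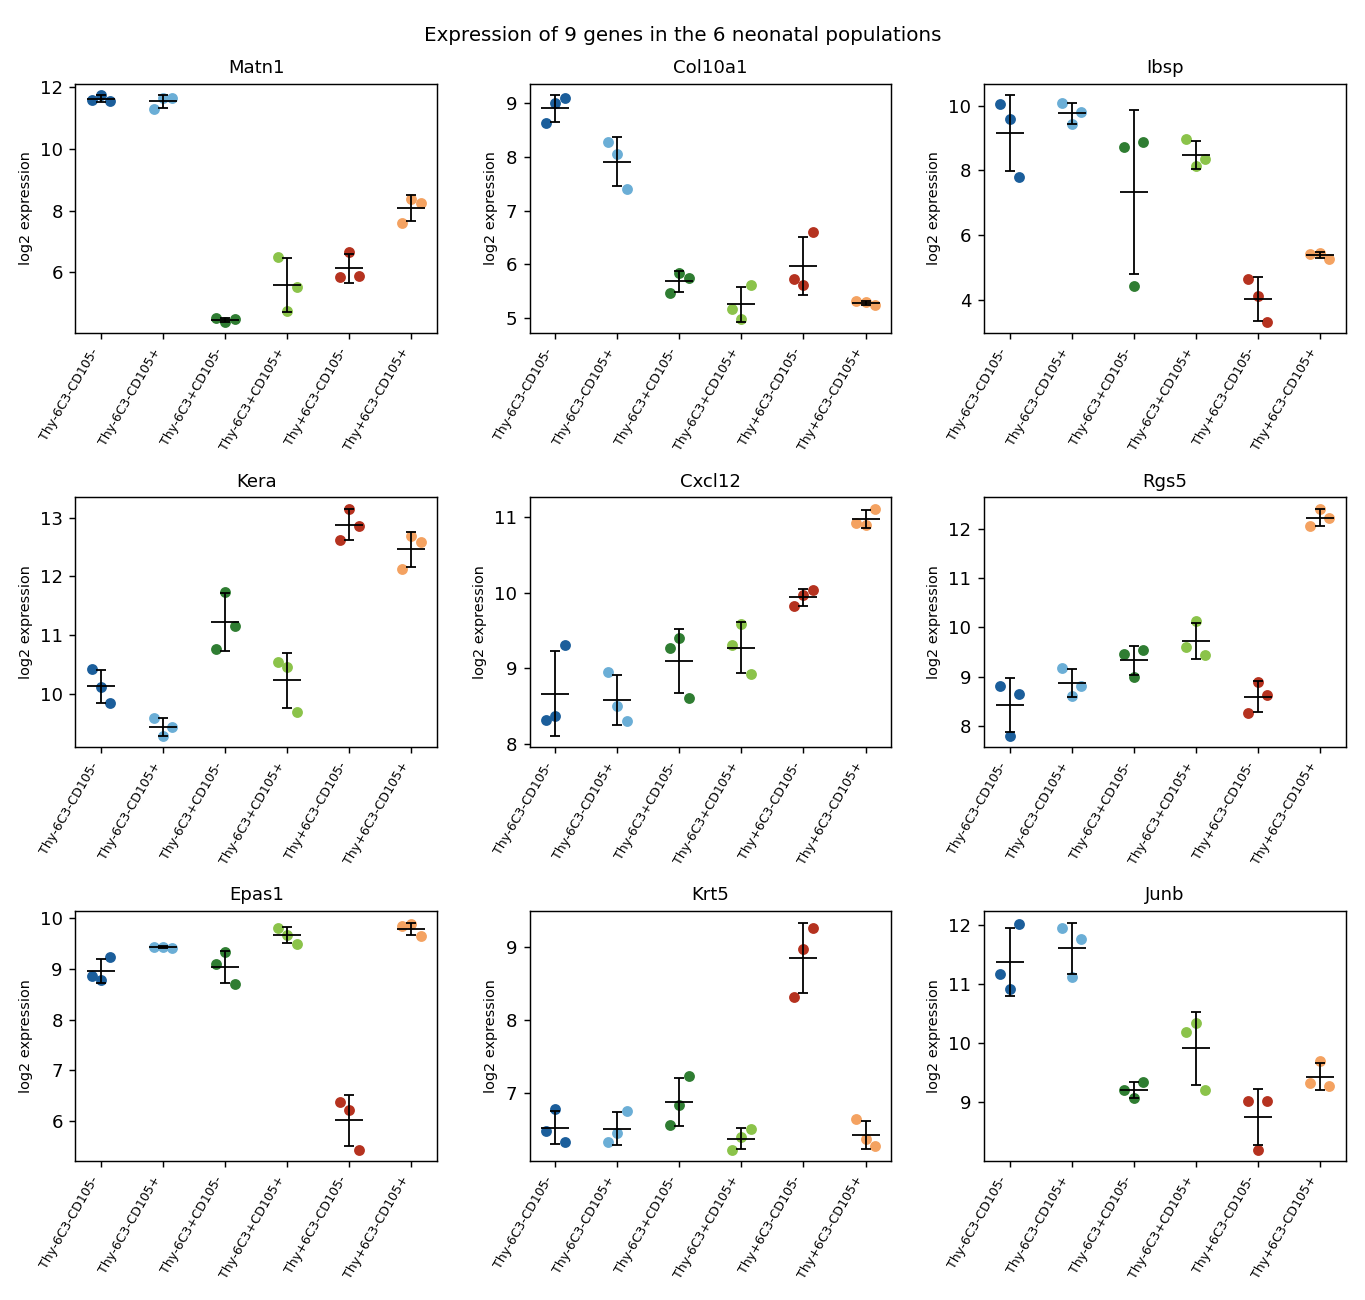
Log2 expression of 9 genes on each array of the 6 neonatal populations, with the mean and SD of 3 arrays in black. Matn1 and Col10a1 are highest in the Thy-6C3- populations, Kera is highest in the Thy+ populations, Rgs5 is highest in Thy+6C3-CD105+ cells and Krt5 in Thy+6C3-CD105- cells, where Epas1 is lowest.

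In the 6C3 step in Thy-CD105+ cells, cartilage genes were lower in the 6C3+ population and some fibrous genes were higher. Of 23 chondrocyte genes 11 fell (16 adjusted over the list alone, median -1.35). Matn1 went from 11.54 ± 0.20 in Thy-6C3-CD105+ to 5.59 ± 0.88 in Thy-6C3+CD105+ cells (adjusted p = 1.40e-08), Epyc changed by -5.62 ± 0.26, Matn3 by -3.71 ± 0.23 and Snorc by -3.07 ± 0.43. Of 8 hypertrophic chondrocyte genes 3 fell (6 fell and 1 rose adjusted over the list alone), including Col10a1 (-2.66 ± 0.27) and Ihh (-1.92 ± 0.23). Of 20 tendon and fibrous genes 3 rose (8 adjusted over the list alone), among them Col14a1, a fibril-associated collagen, from 12.21 ± 0.14 to 13.06 ± 0.06. The metalloprotease list of 18 had 2 members higher (8 higher and 1 lower adjusted over the list alone), and the immediate early list of 18 had 2 lower (5 adjusted over the list alone). Of 41 Wnt pathway genes 3 rose and 3 fell (4 and 8 adjusted over the list alone), the antagonist gene Sfrp1 by -2.41 ± 0.22, the antagonist gene Sfrp5 by -2.52 ± 0.32 and the agonist gene Rspo3 by -1.83 ± 0.29, a call lost with the mean of its probe sets. Gask1b (1.67 ± 0.20) and C1qtnf7 (1.91 ± 0.31) rose, and Efemp1, a fibulin gene (-3.67 ± 0.52), and Fabp7, a fatty acid binding protein gene of glia (-2.51 ± 0.26), fell.

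In this step 247 genes passed the test, 102 higher and 145 lower, 174 of them by at least 2-fold, and 16.3% of genes did not overlap. By camera the chondrocyte (adjusted p = 7.96e-43 and 0.000140 with an estimated correlation), hypertrophic chondrocyte (1.87e-11 and 0.000140), immediate early (2.41e-10 and 0.0290), metalloprotease (2.61e-08 and 0.0113) and tendon lists (4.19e-08 and 0.0290) passed with both settings. The calls of the proliferation, ribosomal protein, osteoclast, articular and synovial, TGF beta, Schwann and neural crest, osteoblast and Wnt lists (adjusted p between 7.61e-06 and 0.0272) were lost, with adjusted p = 0.123, 0.123, 0.102, 0.103, 0.108, 0.103, 0.151 and 0.393 with an estimated correlation. Within the high poly-A set 87 genes passed. The low set left a single array in each group, and its log2 changes correlated with those of the high set at r = 0.561 across genes. The count was 137 and 105 without Thy-6C3-CD105+ replicates 1 and 3, and 151, 108 and 123 without Thy-6C3+CD105+ replicates 1, 2 and 3. It was 652 with array weights (345 higher and 307 lower), 445 without the 2 arrays with extreme hybridization controls and 381 with the compared populations alone.

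The 6C3 step in Thy-CD105- cells showed the cartilage decrease as well. Of 23 chondrocyte genes 14 fell (18 adjusted over the list alone, median -1.68). Matn1 went from 11.62 ± 0.11 in Thy-6C3-CD105- to 4.46 ± 0.06 in Thy-6C3+CD105- cells (adjusted p = 1.26e-09), Epyc changed by -5.35 ± 0.26 and Matn3 by -3.92 ± 0.23. Of 8 hypertrophic chondrocyte genes 5 fell, over all genes and adjusted over the list alone, including Col10a1 (-3.22 ± 0.27) and Ihh (-3.05 ± 0.23). Of 18 osteoblast genes 3 fell (6 adjusted over the list alone), led by Sp7, the osteoblast transcription factor gene osterix, from 8.62 ± 0.60 to 6.88 ± 0.15. Tendon and fibrous genes rose in 5 of 20 cases (10 rose and 2 fell adjusted over the list alone), among them Thbs4 (1.76 ± 0.26) and Col14a1 (0.97 ± 0.14). Of 10 Schwann and neural crest genes 4 fell (4 fell and 1 rose adjusted over the list alone), with S100b at -3.60 ± 0.39 and Fabp7 at -3.01 ± 0.26. Of 28 BMP pathway genes 3 fell (6 fell and 1 rose adjusted over the list alone), and of 18 immediate early genes 4 fell (8 adjusted over the list alone), including Junb (-2.15 ± 0.33). Sfrp5 (-2.71 ± 0.32), Rspo3 (-2.58 ± 0.29), Sfrp1 (-2.18 ± 0.22) and Car8, a carbonic anhydrase relative (-4.36 ± 0.39), fell. Fgf9 (2.11 ± 0.38) and the potassium channel gene Kcnk2 (1.91 ± 0.22) rose, as did Rspo2, a Wnt agonist gene (2.29 ± 0.36). The Rspo2 call was lost when the arrays were grouped by title, a fit that leaves a single Thy-6C3+CD105- array.

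In this step 498 genes passed the test, 226 higher and 272 lower, 348 of them by at least 2-fold, and 17.6% of genes did not overlap. With a common median only, the split was 82 higher and 315 lower, and over the upper part of genes by mean level 256 and 218. The chondrocyte (adjusted p = 1.58e-40 and 0.000106 with an estimated correlation), hypertrophic chondrocyte (3.75e-15 and 6.46e-05), immediate early (2.14e-09 and 0.0295), osteoblast (6.11e-06 and 0.0241), BMP (0.000805 and 0.0295) and Schwann lists (0.000932 and 0.0261) passed with both settings. The tendon list (adjusted p = 2.58e-05) lost its call (adjusted p = 0.0779 with an estimated correlation). So did the proliferation, osteoclast, endothelial, articular and synovial, Wnt, ribosomal protein and interferon lists (adjusted p between 0.00586 and 0.0431), with adjusted p = 0.372, 0.113, 0.135, 0.160, 0.486, 0.372 and 0.113 with an estimated correlation. Each poly-A set left a single array in a group of this step, and the log2 changes of the 2 sets correlated at r = 0.538 across genes. Grouping by title also left a single Thy-6C3+CD105- array, so its lower count is not given. The compared populations alone gave 204. The 2 6C3 steps share no arrays. Of their called genes 84 were higher in both, where independent calls give 1.27, 130 were lower in both, where they give 2.17, and none went opposite ways (r = 0.602 across genes, which are not independent replicates).

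In the CD105 step in Thy+6C3- cells, pericyte and smooth muscle genes were higher in the CD105+ population. Of 12 list members 6 rose (9 adjusted over the list alone, median 1.19), with Rgs5 at 12.22 ± 0.17 in CD105+ and 8.59 ± 0.32 in CD105- cells (adjusted p = 1.07e-06), Notch3 at 3.05 ± 0.42, Kcnj8 at 2.40 ± 0.22 and Myh11, smooth muscle myosin, at 2.35 ± 0.28. Epas1, a hypoxia-inducible transcription factor gene, stood at 9.79 ± 0.12 against 6.01 ± 0.50, a rise of 3.79 ± 0.23 (adjusted p = 9.45e-08). Vgll3 (3.33 ± 0.36), the amine oxidase gene Aoc3 (3.12 ± 0.49), and the limb transcription factor genes Twist2 (2.07 ± 0.30) and Shox2 (2.04 ± 0.33) rose. Keratin genes fell, Krt5 from 8.84 ± 0.48 to 6.43 ± 0.19 (adjusted p = 2.98e-05), Krt14 by 2.18 and Krt15 from 7.59 ± 0.95 to 5.13 ± 0.22, 3 of 12 keratinocyte genes over all genes and 4 adjusted over the list alone. The Krt15 call was lost without Thy+6C3-CD105+ replicate 2 or 3, and the Krt14, Krt15, Laptm5, Gdf10 and Matn1 calls were lost with the compared populations alone. Laptm5 fell by 2.36, a call lost without replicate 2 or 3 of Thy+6C3-CD105+ or replicate 3 of Thy+6C3-CD105-. With the mean of its probe sets it fell by 0.627 and did not pass, nor did it pass without the 2 arrays with extreme hybridization controls. Of 28 BMP pathway genes 3 rose (7 rose and 1 fell adjusted over the list alone), including Gdf10 (0.97 ± 0.15). Of 19 haematopoietic support genes 1 rose (5 rose and 1 fell adjusted over the list alone). Matn1 was 1.95 ± 0.34 higher in CD105+ cells, 2 of 23 chondrocyte genes rising and 1 falling (3 and 2 adjusted over the list alone), and that list did not pass (adjusted p = 0.106).

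In this step 185 genes passed the test, 150 higher and 35 lower, 150 of them by at least 2-fold, and 24.8% of genes did not overlap. The pericyte (adjusted p = 1.17e-14 and 0.00449 with an estimated correlation), keratinocyte (0.000170 and 0.0154), BMP (0.000550 and 0.0278) and haematopoietic support lists (0.00462 and 0.0278) passed with both settings, the keratinocyte call being lost over the upper part of genes by mean level. The metalloprotease, immediate early and adipocyte lists (adjusted p = 0.00462, 0.00900 and 0.0321) did not, with adjusted p = 0.163, 0.381 and 0.15 with an estimated correlation. Within the high poly-A set 59 genes passed. The low set left a single array in each group, and its log2 changes correlated with those of the high set at r = 0.407 across genes. Single arrays moved the count, to 87 and 78 without Thy+6C3-CD105+ replicates 2 and 3, and to 733 (448 higher and 285 lower) and 92 without Thy+6C3-CD105- replicates 1 and 3, the last of which has Eng near the CD105+ level. It was 308 with a common median only, 45 over the upper part of genes by mean level, 2567 with array weights, where most were lower (887 higher and 1680 lower), 110 without the 2 arrays with extreme hybridization controls and 68 with the compared populations alone.

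The CD105 step in Thy-6C3- cells called 1 gene, and hypertrophic chondrocyte genes were lower as a list. Ednrb, an endothelin receptor gene, fell from 6.82 ± 0.22 in CD105- to 4.80 ± 0.46 in CD105+ cells (adjusted p = 0.00734). The median change of the 8 hypertrophic chondrocyte genes was -0.63, with none past the test over all genes and 2 lower adjusted over the list alone. Col10a1 stood at 7.92 ± 0.46 in CD105+ and 8.91 ± 0.25 in CD105- cells (-0.99 ± 0.27), and the difference of Ihh was -0.93 ± 0.23. The list passed with the preset and the estimated correlation (adjusted p = 1.31e-09 and 0.000580), with medians of -0.86 and -0.71 within the high and low poly-A sets, and its call was lost over the upper part of genes by mean level. The proliferation, BMP, endothelial, Schwann and osteoblast lists (adjusted p = 1.44e-07, 0.0185, 0.0185, 0.0185 and 0.0187) lost their calls, with adjusted p = 0.154, 0.154, 0.168, 0.154 and 0.222 with an estimated correlation. By limma 318 of 18193 genes had an unadjusted p under 0.05, a smaller share than the 0.05 that chance gives on average. For 6.33% of genes the groups did not overlap, where chance gives 10%. Each poly-A set left a single array in a group of this step, so no count is given within them. The log2 changes of the 2 sets correlated at only r = 0.171 across genes. The count was 0 without CD105- replicate 1 or CD105+ replicate 2, both of which ended the Ednrb call, and 2 without CD105+ replicate 1. It was 0 over the upper part of genes by mean level or with the compared populations alone, and 2 with array weights or without the 2 arrays with extreme hybridization controls. The mean of all probe sets also gave 2, neither of them Ednrb, whose call was lost. The higher of these was Eng, the gene of the antigen sorted on, which was also the gene gained with array weights.

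The CD105 step in Thy-6C3+ cells called 0 genes by limma, where the smallest adjusted p was 1. Of 18193 genes 498 had an unadjusted p under 0.05, again a smaller share than the 0.05 that chance gives on average. The median change was 0.26 for the 23 chondrocyte genes and 0.35 for the 25 proliferation genes, with no member past the test over all genes or adjusted over the list alone. Camera called both lists and the metalloprotease list with the preset correlation (adjusted p = 2.93e-06, 1.37e-09 and 0.00419) and none of them with an estimated correlation (adjusted p = 0.212, 0.212 and 0.262). The high poly-A set called no gene, with 5 residual degrees of freedom, and the low set left a single array in each group. The log2 changes of the low set correlated negatively with those of the high set, at r = -0.236 across genes. The mean of all probe sets called 1, Eng, the gene of the antigen sorted on. On simulated data of this comparison 49% of genes changed by 1 and 92% of genes changed by 2 on the log2 scale were recovered. That simulation used independent noise, while the real arrays deviated together, so these shares do not measure what the real comparison could detect.

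The CD105 differences were compared between backgrounds by interaction tests. Between Thy+6C3- and Thy-6C3- cells 49 genes differed in their CD105 step, 44 with a more positive and 5 with a more negative step in Thy+ cells. Pericyte and smooth muscle genes made up 6 of the 44 (8 adjusted over the list alone, median difference 1.38), and 3 keratinocyte genes were among the 5. The pericyte (adjusted p = 1.68e-12 and 0.00793 with an estimated correlation), keratinocyte (0.00125 and 0.0232), hypertrophic chondrocyte (5.41e-05 and 0.00793) and BMP lists (5.41e-05 and 0.0146) passed. Each poly-A set left single arrays in the groups of this interaction, so no count is given within them. Across genes the values of the poly-A sets correlated at r = 0.418 for this interaction and -0.053 for the CD105 by 6C3 interaction. The count was 30 and 31 without Thy-6C3-CD105- replicates 1 and 3, 25 without Thy-6C3-CD105+ replicate 3, 32 and 30 without Thy+6C3-CD105+ replicates 2 and 3, and 104 without Thy+6C3-CD105- replicate 1. It was 86 with a common median only, 12 over the upper part of genes by mean level, 77 with the mean of all probe sets and 645 with array weights, where most steps were more negative (225 more positive and 420 more negative). Between Thy-6C3+ and Thy-6C3- cells 0 genes differed by limma, and 543 of 18193 had an unadjusted p under 0.05, a smaller share than chance gives on average. The hypertrophic chondrocyte list differed (median 0.76, adjusted p = 1.75e-05 and 0.00728 with an estimated correlation). Its member Col10a1 was at 4.98 to 5.85 on Thy-6C3+ and 5.24 to 6.60 on Thy+6C3- arrays, below the median gene mean of 6.76. A fall of that gene with CD105 could hardly show there, which limits both interactions for it. The other list members were also lower in Thy+6C3-CD105- than in Thy-6C3-CD105- cells. Low levels may thus limit the list results of both interactions too, though Pth1r was at 9.22 or higher on every neonatal array. Across genes the CD105 changes of Thy-6C3- cells correlated negatively with those of Thy+6C3- (r = -0.344) and of Thy-6C3+ cells (r = -0.172), and those of the last 2 positively with each other (r = 0.362). The poly-A sets were unequally divided between CD105+ and CD105- arrays in Thy-6C3- cells, and equally in the last 2. The CD105 changes of Thy-6C3+ cells also correlated negatively between the sets (r = -0.236). These correlations thus cannot separate the CD105 steps from deviations shared within the sets.

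**Figure D3:**
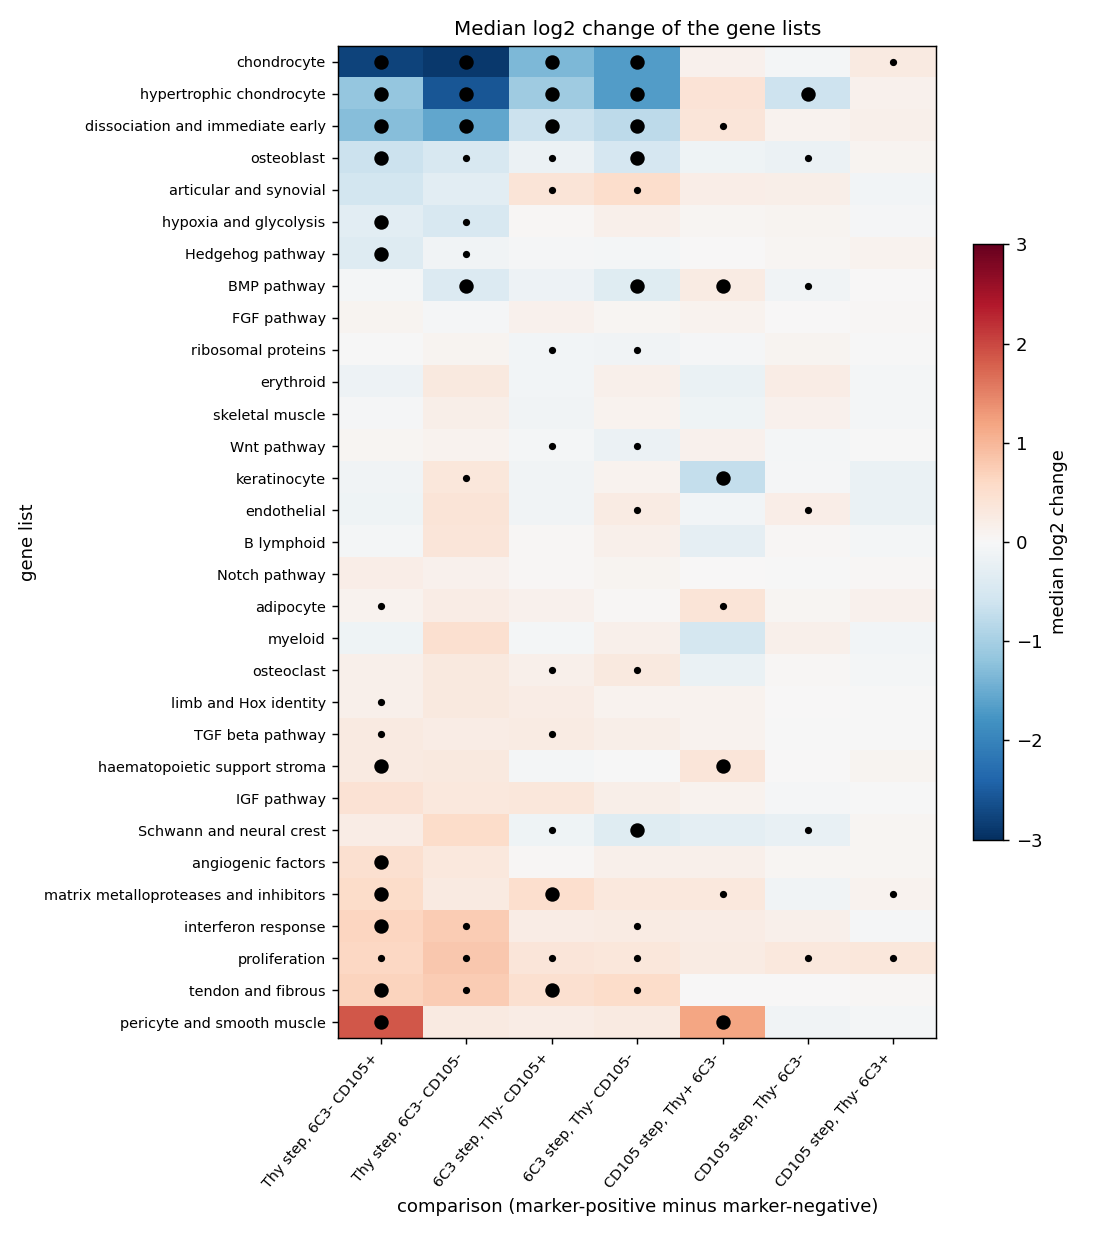
Median log2 change of the 31 gene lists in the 7 comparisons, as colour. Small dots mark camera calls with the preset correlation only and large dots calls that also held with an estimated correlation, and the chondrocyte list shows the deepest decrease in both Thy steps.

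The first 2 principal components held 35.7% and 18.6% of the variance of the neonatal arrays. Thy-6C3- arrays and Thy+6C3- arrays lay apart, and Thy+6C3-CD105- replicate 3 lay farthest out on the first component. That array had an array weight of 0.174 and a mean correlation of 0.936 with its own population. Its Eng level goes against its CD105- label, while its Rgs5 and Epas1 levels are on the side of its replicates. Thy-6C3+CD105- replicate 2 had a hybridization control mean of 6.05, where the other arrays had 9.81 to 11.2. The highest of these was Thy+6C3-CD105- replicate 3. The fits without the 2 arrays with extreme controls and without that replicate alone are therefore not separate checks.

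**Figure D4:**
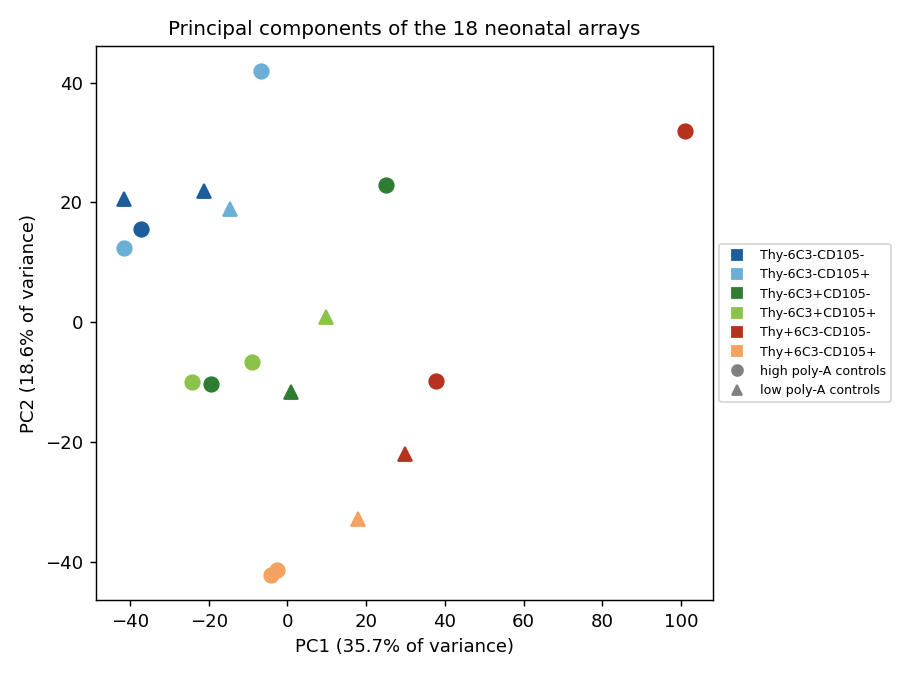
Scores of the 18 neonatal arrays on the first 2 principal components, coloured by population, with circles for arrays of high and triangles for arrays of low poly-A control signal. Thy+6C3-CD105- replicate 3 lies alone at the right, and both symbols occur in every population.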

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

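The tests of splits within backgrounds, of an outlying array, of pericyte and smooth muscle cells and of keratinocyte RNA below were chosen after the results were seen, while the interaction test and its other splits were planned. The CD105 step differed between Thy+6C3- and Thy-6C3- cells for 49 genes by the interaction test. The genes with the largest differences by the rule for named genes were Vgll3, with a log2 difference between the steps of 3.60 ± 0.52 (SE, adjusted p = 0.00343 from limma), Notch3 at 3.38 ± 0.60 (0.0155), Apela, a peptide hormone gene, at 3.35 ± 0.51 (0.00486), Epas1 at 3.31 ± 0.33 (0.000185), Krt15 at -3.23 ± 0.64 (0.0368), Laptm5 at -3.18 ± 0.64 (0.0447), Krt5 at -2.40 ± 0.35 (0.00343) and Krt14 at -2.10 ± 0.38 (0.0209). The calls of Vgll3, Apela, Epas1 and Krt5 held with each array left out. The Notch3 call was lost without Thy-6C3-CD105- replicate 1 or Thy-6C3-CD105+ replicate 3, Krt15 and Laptm5 each lost theirs on leaving out any of 10 single arrays, and Krt14 on leaving out any of 6. Of 100 splits of the 12 arrays, 3 gave at least 49 genes, the real one included. These splits exchange arrays between Thy+ and Thy- populations, which differ in many genes, so their share does not measure chance for the interaction. The highest other split gave 407, several times the real count, which points to a structure of the samples. With the CD105 labels rearranged within each background only, 5 of 100 splits, drawn at random, gave at least 49 genes, the real one included, and the highest other gave 59, so chance is not excluded at a share of 0.05. The 4 other splits with at least 49 genes all kept the real grouping of Thy+6C3- arrays and rearranged the Thy-6C3- arrays. Splits that broke the Thy+6C3- grouping gave at most 1 gene. The count thus followed the Thy+6C3- step. The share depends on how many splits keep that grouping, so it cannot decide on chance for the difference between the steps.

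The CD105 step called 185 genes in Thy+6C3- cells, 1 in Thy-6C3- cells and 0 in Thy-6C3+ cells, and pericyte and smooth muscle genes were among those that rose. A single outlying array is argued against as the whole source, since at least 78 genes passed with each of the 6 arrays left out in turn, where the other backgrounds reached at most 2 genes with any array left out. Without the array labelled Thy+6C3-CD105- replicate 3, whose Eng level of 8.58 goes against its label, 92 passed. Cells of pericyte or smooth muscle type in the Thy+6C3-CD105+ gate cannot be told apart from progenitors that express these genes. Of the 8 list members not named for this step, 5 were higher at an unadjusted p under 0.05, a count that the list result already held, so it decides nothing. Whether the gate, which excluded CD45, Ter119 and Tie2 and required integrin alpha V, removed such cells was not tested. A difference between the sorted populations also stays open, untested.

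The keratin genes Krt5, Krt14 and Krt15 were higher in Thy+6C3-CD105- cells than in both neighbouring populations, with Krt5 at 8.31, 8.97 and 9.25 on the 3 arrays. Krt14 and Krt15 were highest on replicate 2, at 7.71 and 8.65 against 6.34 and 6.54, and 6.79 and 7.32. A single outlying array is argued against as the whole source, since the median change of the 3 genes in the CD105 step was -1.924 without replicate 2, the smallest with any of the 6 arrays left out, and -2.41 with all. These changes are approximate, since Krt14 and Krt15 stood near background in Thy+6C3-CD105+ cells, at 4.68 and 5.13. RNA of keratinocytes cannot be told apart from expression in the sorted cells, which the gate required to carry integrin alpha V and Thy. Of the 9 other list members 1, Sfn, was higher in both comparisons at an unadjusted p under 0.05, but only 3 of the 9 reached the median gene level, 0 of which were higher in both. Epcam, one of these 3, stood at 10.71 against 10.07 and 9.36.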

How the results depend on the processing

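The spike-in block and the fit without the 2 arrays with extreme hybridization controls were chosen after seeing the data, and the other alternatives were planned. The 320 named gene results had 5774 values under the alternatives, of which 5234 kept direction and call, 528 lost the call, 7 gained it, all of them Eng in a CD105 step, and 5 reversed. The 83 list results had 1679, of which 1460 kept both, 219 lost the call and 0 reversed, and an estimated correlation kept 37 and lost 46. With the spike-in block 318 gene and 75 list results kept both, and 2 and 8 lost the call. That block gave 245 genes for the CD105 step in Thy+6C3- cells and 53 for the CD105 by Thy interaction. Camera has no robust variance, so list results were not run with it. Signal near background limits genes such as Krt14, at 4.68 to 4.94 outside Thy+6C3-CD105- cells. The counts of genes past the test that moved by over 1.5 times follow, and unless said otherwise the cause was not tested. Array weights gave 2 for the CD105 step in Thy-6C3- cells, 2567 in Thy+6C3- cells, 2889 for the Thy step in CD105+ cells, 652 for the 6C3 step in CD105+ cells, 3898 for any difference and 645 for the CD105 by Thy interaction. A common median only gave 308 for the CD105 step in Thy+6C3- cells and 86 for the interaction. Leaving out the less expressed genes, with fewer genes tested, gave 0 and 45 for the CD105 step in Thy-6C3- and Thy+6C3- cells and 12 for the interaction. The mean of all probe sets gave 2 and 1 for the CD105 step in Thy-6C3- and Thy-6C3+ cells, Eng being 1 of them in each, and 77 for the interaction. Without the 2 arrays the CD105 step gave 2 and 110 in Thy-6C3- and Thy+6C3- cells, the Thy step in CD105- cells 2118 and the 6C3 step in CD105+ cells 445. The arrays of the compared populations alone gave 0 and 68 for these CD105 steps, 1182 for the Thy step in CD105- cells, and 381 and 204 for the 6C3 step in CD105+ and CD105- cells. They gave 1813 for the Thy step in CD105+ cells, a smaller move. Some counts thus rose and others fell. Such fits use fewer arrays and their own estimate of the spread, and which of these moved the counts was not tested. Grouping by title gave 167 for the 6C3 step in CD105- cells. The replicate number as a block gave 307 for the CD105 step in Thy+6C3- cells, and 1, 0, 1239, 3531, 241 and 506 for the other steps, 69 and 0 for the interactions. Replicate numbers did not pair the arrays: 0 comparisons had every pair correlated above 0.1, and 7 of 18 arrays were closest to arrays of their own number, so the block is given here only. Leaving out 1 array gave 0 to 2 for the CD105 step in Thy-6C3- cells, 78 to 733 in Thy+6C3- cells, 781 to 1033 and 1549 to 4218 for the Thy step in CD105+ and CD105- cells, 105 to 209 for the 6C3 step in CD105+ cells and 25 to 104 for the CD105 by Thy interaction. Reversed were Armc8 in the CD105 step of Thy+6C3- cells, 0.073 with the mean of its probe sets, and Panx3 without shared probe sets, 0.099 and 0.091 in the Thy step of CD105+ and CD105- cells and 0.064 and 0.28 in the 6C3 step.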

Other observations

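The tests of shared deviations and the splits within backgrounds below were chosen after the result was seen, and the other splits of the arrays were planned. The array labelled adult Thy+6C3+CD105+, a single array with no test and no replicate check, stood apart from the neonatal means in cartilage and cell cycle genes. Its Enpep level of 8.43 goes against the 6C3+ label. Of 23 chondrocyte genes 21 were higher (median 0.98 above the mean of the 6 neonatal populations), though Matn1 was at 4.95. That mean includes the Thy+ and 6C3+ populations, in which cartilage genes were lower. Snorc at 12.25 lay within the neonatal range of 7.42 to 12.48, and Cytl1 at 13.52 above its range of 7.99 to 12.48. The hypertrophic chondrocyte list had a median of -0.898, above 0.1% of random lists, with 3 of 8 genes higher, and the pericyte list one of -0.939, with 2 of 12 higher. The adipocyte list did not stand out (median 0.002, above 68.35% of random lists, 8 of 13 higher), but its members Fabp4, a fatty acid binding protein, and Pparg, the adipocyte transcription factor, stood at 10.01 and 8.89, above the neonatal ranges of 4.90 to 7.72 and 4.98 to 6.34. They were picked from its largest differences. All 25 proliferation genes were lower (median -1.86), including Mki67 at 7.09 against 8.93 to 11.05. Tendon and fibrous genes had a median of -1.08 (2 of 20 higher), with Kera at 4.93 against 9.29 to 13.15, limb and Hox genes one of -0.98 (6 of 24 higher), with Hoxd13 at 4.96 against 8.69 to 10.57, and osteoblast genes one of -0.71 (4 of 18 higher), with Col1a1 at 9.29 against 12.13 to 14.28, but Omd at 12.89 against 7.45 to 11.70 and Dlx5 at 8.77 against 5.81 to 7.87. All 18 immediate early genes were higher (median 1.44). The chondrocyte and immediate early medians lay above all of 10000 random lists of the same size matched on mean level, and the proliferation, tendon, limb and osteoblast medians below all of them, which describes this array and tests no condition. Across genes the array correlated with the neonatal means at r = 0.952 for Thy-6C3-CD105- down to r = 0.905 for Thy+6C3-CD105-. Its labels name both limbs and sternum and ear, so age and tissue cannot be separated.

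Some members of lists that did not pass camera changed in the Thy steps. Of 12 IGF pathway genes 3 rose among CD105+ cells and 4 rose and 4 fell among CD105- cells (6 and 4, and 4 and 4, adjusted over the list alone; adjusted p = 0.163 and 0.991), with Igfbp2, an IGF binding protein gene, 2.59 ± 0.44 and 1.96 ± 0.44 higher and Igf1 1.53 ± 0.26 and 1.57 ± 0.26 higher. Of 18 FGF pathway genes 2 rose and 3 fell among CD105+ cells (4 and 3 adjusted over the list alone), with Spry1, a feedback inhibitor, up by 1.69 ± 0.33 and Etv5, a target transcription factor gene, at -1.65 ± 0.33. Of 18 Notch pathway genes 2 rose and 1 fell there (3 and 2 adjusted over the list alone), the targets Hey2 (1.94 ± 0.18) and Heyl (1.59 ± 0.24) being higher. The B lymphoid, erythroid, FGF, IGF, myeloid, Notch and skeletal muscle lists passed camera in none of the 7 steps.

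Arrays of different populations deviated together from their population means. A processing batch marked by the poly-A controls is a candidate explanation: the deviations correlated with a mean r of 0.139 within and -0.148 between the poly-A sets, a difference of 0.287 (exact permutation p = 0.00274, one-sided, 729 rearrangements within populations). Shared replicate numbers, as from litters sorted together, are not supported, with a difference of 0.018 (exact permutation p = 0.348, one-sided, 46656 rearrangements). No biological explanation was tested, since the labels do not give the litter of an array.

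Other splits of the arrays were counted for each test. For any difference among the 6 populations 1 of 100 splits, the real one with 1845 genes, gave as many, and the highest other gave 14, so chance is excluded. For the CD105 by 6C3 interaction the real count was 0, which every split reaches (100 of 100), so the count of splits says nothing about chance there. The highest was 180 over all splits and 945 with the CD105 labels rearranged within each background, which points to a structure of the samples. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real counts and the highest other split were 1211 and 0 for the Thy step in CD105+ cells, 3271 and 0 in CD105- cells, 247 and 0 for the 6C3 step in CD105+ cells, 498 and 0 in CD105- cells, 185 and 0 for the CD105 step in Thy+6C3- cells, 1 and 1 in Thy-6C3- cells (2 of 10 splits) and 0 and 0 in Thy-6C3+ cells (10 of 10 splits).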
